A study of Mus musculus with 9 samples.

How the data were processed

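The series compares sorted mouse skin cells of 2 Flg genotypes, with 5 wt/wt and 4 ko/ko samples, each with its own identifier in its title, taken here as separate animals. Flg encodes filaggrin, a structural protein of the cornified layer of the epidermis. Per the labels' protocols, cells negative for CD45, the pan-leukocyte surface protein, and positive for CD49f, the integrin alpha-6 chain, were sorted by flow cytometry. Polyadenylated RNA was amplified over 13 cycles with a SMART method, cut and tagged with a transposase, and sequenced on a NextSeq 500.

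The deposited table holds raw read counts per gene that the authors made, 1 column per sample. Per the submitters' processing notes, GSNAP, featureCounts 1.6.2 and the mm10 genome were used. The table's name gives Ensembl release 87 for the gene models. Strand handling, multi-mapped reads and duplicate handling are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. The exon length per gene is another column deposited by the authors. Of 49763 rows, 92 are synthetic spike-in sequences and were left out, which left 49671 gene rows. Gene symbols, GC content and coordinates were matched by identifier to GENCODE mouse release M21, and 49326 rows had a symbol. Chromosome, start and end were identical there for 45128 rows; positions printed are those of the authors' table.

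Totals ran from 15601859 to 23200440 counts per library, so 1 count equals 0.0431 to 0.0641 CPM of the library total. CPM of genes and lists use library sizes adjusted by TMM, while this floor, the Gm10800-group and Malat1 CPM and all shares use library totals. The labels name no molecular identifiers, so intervals and floors cover counting error only. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was at least 23.9 over genes with 20 or more counts in the pair. Genotype came from the labels, and replicate numbers follow accession order and pair nothing.

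Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on genotype, TMM factors, glmQLFit with robust=TRUE, a two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment, threshold 0.05. The filter kept 18435 genes and removed 31236. Log2 fold changes are ko/ko over wt/wt, and the standard error (SE) is the absolute log2 fold change over the square root of F. On data simulated from these libraries over 18435 genes, the test recovered 24% of 100 genes changed 2-fold and 73% of 100 changed 4-fold, with 3 false among 100 calls. With no gene changed, 4.78% had an unadjusted p under 0.05. The simulation drew each gene independently, without the structure that genes share within the real libraries. Its rates of recovery and false calls may therefore not hold for the real data.

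Before the data were examined, 37 gene lists, the tests, a first set of other settings and the rule for named genes were fixed. The 35 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01). The rule names Flg in every sample, all genes with an adjusted p under 0.05 and then the genes with the smallest p-values up to 24 in all, stated not to pass. It adds up to 4 members of each described list and 10 fixed markers as values. Genes named outside it and its lists were chosen after their values were seen. A set of 4 further lists was made after the data had been examined: tendon and cartilage matrix, lymphatic endothelial, cytoplasmic ribosomal protein, and other macrophage and dendritic cell genes.

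That first set held RLE, upper-quartile or no factors, no or a stricter filter, DESeq2 1.42.0, limma voom with sample quality weights, robust=FALSE, 1 surrogate variable (sva 3.50.0), removal of mitochondrial and the 20 most abundant genes, other thresholds and each library left out. Settings added after seeing the data were legacy=FALSE, voom without weights, 3 sets of left-out libraries, a covariate for an 11-gene group around Gm10800, and removal of loess trends (span 0.3) on exon length or GC. Other groupings of the 9 libraries into 4 and 5 were refitted for 100 splits drawn with a fixed seed, the real one included; the planned count of all splits for the spread between animals was limited in the same way.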

Results

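The study asked how loss of filaggrin alters gene expression in keratinocytes. RNA was sequenced from CD45-negative, CD49f-positive skin cells of 5 wt/wt and 4 ko/ko mice, with totals of 15601859 to 23200440 counts per library. Values are counts per gene as deposited, scaled here to CPM with TMM-adjusted library sizes.

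Flg itself had 0 to 6 counts in every library of both genotypes, too few to check the genotype labels. Flg (ENSMUSG00000102439, mm10 chromosome 3, 93273523 to 93293686, plus strand, protein-coding) had 0, 0, 6, 2 and 4 counts in wt/wt replicates 1 to 5 and 2, 0, 0 and 4 counts in ko/ko replicates 1 to 4. The pooled ratio of ko/ko to wt/wt was 0.684, with an exact 95% interval of 0.211 to 1.97. The neighbouring late-epidermal genes were also low: Lor, a major cornified envelope protein, averaged 0.264 ± 0.0763 CPM (SD, n = 5) in wt/wt, and Hrnr, a filaggrin-related gene, averaged 0.151 ± 0.226 CPM (SD, n = 5). Of 33 late cornified envelope and fused S100 genes, 3 were expressed enough to be tested.

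The stromal transcripts Gsn and Dcn exceeded Krt14 in every library of both genotypes. Gsn, an actin-severing protein, was the most abundant gene at 23677 ± 8123 CPM (SD, n = 5) in wt/wt and 23889 ± 5440 CPM (SD, n = 4) in ko/ko, and Dcn, a matrix proteoglycan of fibroblasts, ranked second. Krt14, the basal keratin, averaged 1146 ± 399 CPM (SD, n = 5) in wt/wt and 1202 ± 283 CPM (SD, n = 4) in ko/ko. Fixed fibroblast markers took 3.63% to 8.20% of counts and basal keratinocyte markers 0.356% to 0.599%. Dcn lay above Krt14 in 9 of 9 libraries. Neither share differed between genotypes past the threshold in an exact permutation test over 10 library measures (adjusted p = 0.357 for the keratinocyte and 0.665 for the fibroblast share, two-sided). Unadjusted p in that test was 0.0556 and 0.532, with mean keratinocyte shares of 0.525% in ko/ko and 0.416% in wt/wt. The smallest unadjusted p possible was 0.00794, so a single differing measure could not pass after adjustment. A difference in these shares is therefore not excluded.

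**Figure D1:**
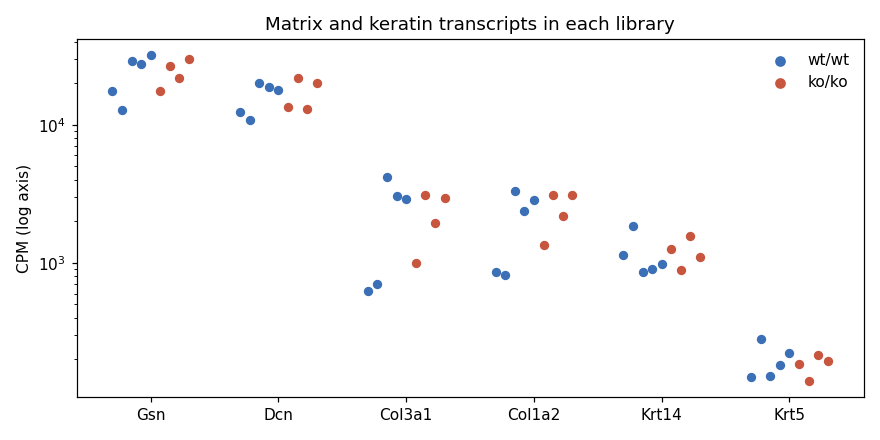
CPM on a log axis for 4 matrix or stromal transcripts and 2 keratins, 1 point per library, wt/wt in blue and ko/ko in red. Dcn lies above Krt14 in 9 of 9 libraries.

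The genotypes differed in 1 gene by edgeR's quasi-likelihood test after adjustment. Clmp, a cell adhesion molecule, was higher in all 4 ko/ko libraries, at 40.2 ± 3.78 CPM (SD, n = 4) against 16.4 ± 2.23 CPM (SD, n = 5), a log2 fold change of 1.29 (SE 0.15, edgeR adjusted p = 0.0418). Clmp (ENSMUSG00000032024) lies on mm10 chromosome 9 from 40685962 to 40785319 and overlaps predicted genes. No gene was lower at this threshold (0 genes), while 2816 of 18435 genes had an unadjusted p under 0.05, against 922 expected by chance. Of these, 1633 were higher and 1183 lower in ko/ko, or 2124 and 598 when scaled by library size alone, 1403 and 1409 with each library's trend on exon length removed, and 1542 and 1430 with that on GC removed. Among the same libraries DESeq2 called 438 genes higher and 192 lower, and limma voom with quality weights called 1217 higher and 585 lower. Clmp lost its call in 8 of the 9 fits that left out 1 library, with adjusted p up to 0.190 (without wt/wt replicate 5), and kept it without ko/ko replicate 4, where 12 genes were higher. It also lost its call with the length trend removed (adjusted p = 0.0540) and without the 3 libraries richest in Gm10800-group reads (0.0888), where 7 other genes were higher. The log2 fold change was 1.30 and 1.20 there and 1.24 to 1.36 in the fits that left out 1 library.

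The next 23 genes by p-value did not pass, with edgeR adjusted p from 0.0670 to 0.0951, and none of them overlapped between genotypes. DESeq2 and weighted voom each called all 24, 22 as higher and 2 as lower. Across all genes tested, 6.25% had no overlap, against 1.59% by chance. Of the 24 genes, 22 had higher and 2 lower values in ko/ko. Pkd2, which encodes polycystin-2, a cation channel, averaged 211 ± 19.8 CPM (SD, n = 4) against 99.0 ± 19.9 CPM (SD, n = 5). Rab21, an endosomal GTPase, had a log2 fold change of 1.19 (SE 0.17). Pura, a nucleic-acid-binding protein, had 1.29 (SE 0.19). Transcriptional regulators in this set were Tead1 (0.99, SE 0.16), Foxo1 (0.87, SE 0.15), Foxc1 (0.95, SE 0.17), Zfhx3 (0.96, SE 0.17) and Thra (0.76, SE 0.13). Pard3, a cell polarity protein, had 0.94 (SE 0.16), and Gxylt2 had 1.36 (SE 0.20). Map4k3, Capns1 and Dnm1 had 1.09, 0.99 and 0.72. 2700081O15Rik had 1.17 and ENSMUSG00000099597 had 1.12. The lower pair was Lyve1, a hyaluronan receptor of lymphatic endothelium, at 52.2 ± 7.48 CPM (SD, n = 4) against 161 ± 66.1 CPM (SD, n = 5), and Mthfd1l, a mitochondrial folate enzyme, with a log2 fold change of -0.95 (SE 0.17).

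Several of the remaining genes in that set are predicted or overlap other genes, and their counts are uncertain for that reason. The same limit holds for some genes given above: among others, Thra overlaps Nr1d1, Dnm1 overlaps Ciz1 and 2700081O15Rik overlaps Rtn3. 3110080E11Rik, within Csmd1, had 1 count over the wt/wt and 228 over the ko/ko libraries, a ratio of 312 with an exact 95% interval of 55.4 to 12377. That interval covers counting error of the pooled counts and no spread between animals. It had 7.92 CPM in ko/ko replicate 1 against 1.16 to 1.77 CPM in the other ko/ko libraries. Gm43508 (2.66), Gm38197 (2.66), Gm42885 (2.89) and G530011O06Rik (2.37) also had positive log2 fold changes.

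**Figure D2:**
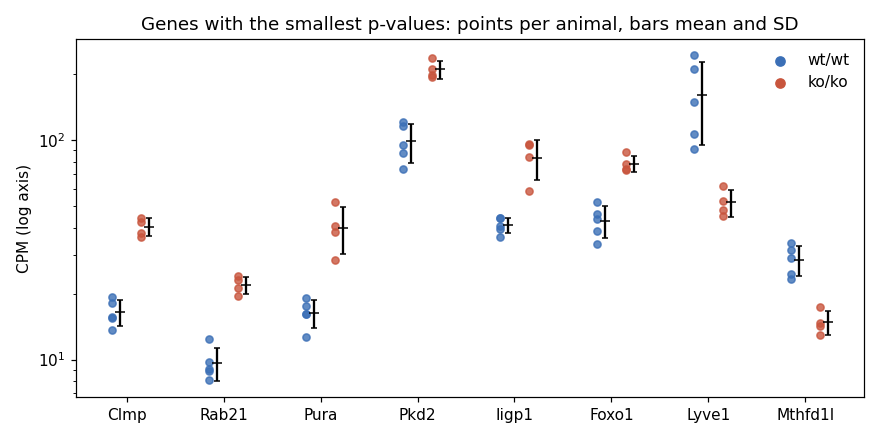
CPM on a log axis for 8 of the 24 named genes, 1 point per animal, wt/wt in blue and ko/ko in red, bars giving mean and SD. Clmp passes the adjusted threshold and the others do not.

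Myeloid and antigen presentation genes were higher in ko/ko as groups. Of 20 tested Langerhans cell and myeloid markers, 19 had positive log2 fold changes (median 2.55, camera adjusted p = 6.17e-10; adjusted p = 0.612 with an estimated correlation). Over all genes 0 members passed edgeR's test, 7 were called by DESeq2 and 3 by weighted voom, and 9 passed edgeR's test adjusted over the list alone; 15 had an unadjusted p under 0.05. C1qc, a complement component of macrophages, averaged 4.85 ± 3.92 CPM (SD, n = 4) against 0.397 ± 0.424 CPM (SD, n = 5). Laptm5 and Fcer1g, genes of haematopoietic cells, had log2 fold changes of 3.52 (SE 0.92) and 2.76 (SE 0.63). The list score was 1.83, 2.18 and 1.34 in ko/ko replicates 1 to 3, but -0.98 in ko/ko replicate 4, and 0.34 in wt/wt replicate 1. Ptprc, which encodes CD45, averaged 2.88 ± 2.88 CPM (SD, n = 4) against 0.433 ± 0.375 CPM (SD, n = 5).

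Of 21 MHC and antigen presentation genes, 15 had positive values (median 0.24, camera adjusted p = 0.0019; adjusted p = 0.612 with an estimated correlation), and 6 passed adjusted over the list alone. The largest values were those of class II genes, among them Cd74 (4.06, SE 1.12), H2-Aa (3.66, SE 0.97), H2-DMb1 (3.36, SE 0.79) and H2-Ab1 (3.03, SE 0.78). This list shares 4 genes with the myeloid list.

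Interferon response genes were higher as a group, with 35 of 44 positive (median 0.29, camera adjusted p = 0.00215; adjusted p = 0.612 with an estimated correlation). Iigp1, an interferon-inducible GTPase, had a log2 fold change of 1.03 (SE 0.16) and Igtp had 0.95 (SE 0.24), and these 2 passed adjusted over the list alone. The group's call ended without ko/ko replicate 2 (median 0.21, adjusted p = 0.0754) and with weighted voom (median 0.17, adjusted p = 0.0859).

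Mitochondrially encoded transcripts were lower as a group, 15 of 15 (median -0.86, camera adjusted p = 1.88e-07; adjusted p = 0.622 with an estimated correlation). mt-Co1, a cytochrome oxidase subunit, averaged 3052 ± 2168 CPM (SD, n = 4) against 8818 ± 3153 CPM (SD, n = 5), and 2 members passed adjusted over the list alone. The estimated correlation between members was 0.80, against the preset 0.01. The mitochondrial share was 1.81% to 2.01% in ko/ko replicates 2 to 4 but 6.30% in ko/ko replicate 1, within the wt/wt range of 2.77% to 7.55%. The mean share was 2.98% in ko/ko against 5.29% in wt/wt (exact permutation p = 0.119, adjusted p = 0.357 over 10 library measures, two-sided). Without ko/ko replicate 1 the group's median was -1.47.

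Hair matrix, cell cycle and cholesterol synthesis genes were also lower as groups, each with a camera adjusted p of 0.0219 and 0 members past the threshold adjusted over the list alone in edgeR's test, in which 4, 1 and 2 members had an unadjusted p under 0.05 as lower. DESeq2 called 0 members of each, and weighted voom called 1, Insig1. With an estimated correlation the adjusted p was 0.901, 0.943 and 0.901. Of 20 hair matrix and inner root sheath genes, 16 were negative, among them the inner root sheath keratins Krt28 (-3.52, SE 1.34), Krt25 (-3.26, SE 1.24) and Krt71 (-3.25, SE 1.14). Of 40 cell cycle genes 34 were negative, Mcm5 with -0.67 (SE 0.28), and of 25 cholesterol synthesis genes 19 were negative, Insig1 with -0.53 (SE 0.18). All 3 calls ended without wt/wt replicate 2, at adjusted p of 0.299, 0.981 and 0.210, where the test direction of the cell cycle list also turned. Other single libraries ended calls as well: the hair matrix call without wt/wt replicate 1 (median -0.92, 0.0530) or ko/ko replicate 2 (-1.01, 0.0754), the cell cycle call without ko/ko replicate 2 (-0.37, 0.0754), and the cholesterol call without wt/wt replicate 3 (-0.18, 0.123) or ko/ko replicate 1 (-0.18, 0.108). With weighted voom the medians were -0.17, 0.06 and -0.10 (adjusted p = 0.597, 0.881 and 0.166). The hair matrix median of -1.01 was -0.45 without wt/wt replicate 2 and -1.55 without ko/ko replicate 3, and the cholesterol median of -0.24 was -0.15 without wt/wt replicate 2.

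**Figure D3:**
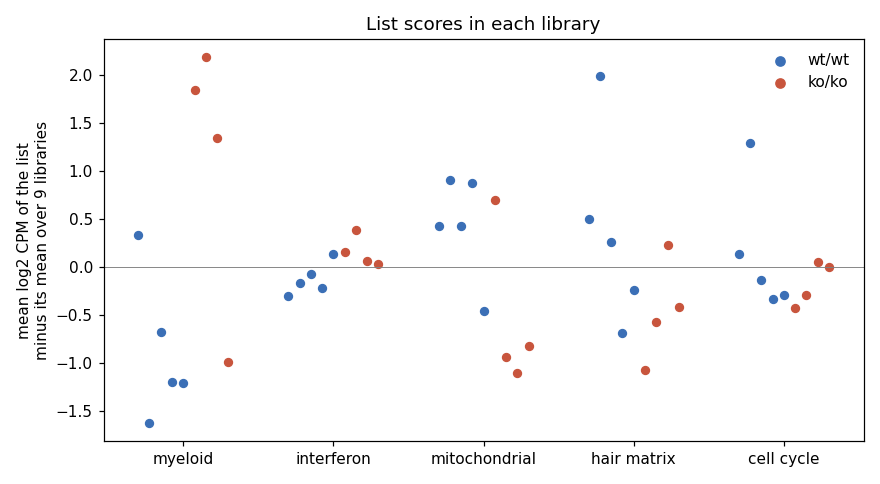
Mean log2 CPM of 5 lists minus its mean over the 9 libraries, 1 point per library in replicate order, wt/wt in blue and ko/ko in red. The myeloid score is high in 3 of 4 ko/ko libraries, and the hair matrix and cell cycle scores are highest in wt/wt replicate 2.

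Of the keratinocyte layer, barrier, junction and wound lists tested with camera, none passed as a group (adjusted p from 0.256 to 0.916), while single members were called by other tools. The counts are of all sorted cells together, so these values cannot separate expression within keratinocytes from the keratinocyte share of the libraries. Basal keratinocyte markers had 12 of 20 members positive (median 0.16, camera adjusted p = 0.502), and Krt5 averaged 183 ± 31.4 CPM (SD, n = 4) in ko/ko against 198 ± 55.4 CPM (SD, n = 5). Itga6, which encodes the CD49f antigen used for the sort, averaged 83.0 ± 14.6 CPM (SD, n = 4) in ko/ko against 53.4 ± 9.04 CPM (SD, n = 5), with an edgeR adjusted p of 0.157 and a DESeq2 adjusted p of 0.0267. Krt1, a suprabasal keratin, had a log2 fold change of 1.05 (SE 0.28, edgeR adjusted p = 0.154, DESeq2 adjusted p = 0.0179), and Krt10, its partner, had 0.08 (SE 0.20). Sprr1b and Sprr1a, small proline-rich envelope precursors, had 1.59 (SE 0.41) and 0.91 (SE 0.36). Of the 3 proline-rich genes tested, too few for a test of the list, all 3 were positive, and these 2 passed edgeR's test adjusted over the list alone (0.00771 and 0.0412) but not over all genes, where DESeq2 called Sprr1b (adjusted p = 0.0148). Of the 3 late envelope genes tested, Prr9 passed as lower over the list alone (-3.77, SE 1.24, adjusted p = 0.0324). It did not pass edgeR's test over all genes (adjusted p = 0.211), and neither DESeq2 nor weighted voom called it. Prr9 averaged 0.313 ± 0.309 CPM (SD, n = 4) in ko/ko against 4.48 ± 5.42 CPM (SD, n = 5), an SD above the mean. Pard3 and Ctnnd1 among tight junction and adherens genes, and Ppp2ca, a phosphatase subunit among filaggrin processing genes, passed as higher over the list alone, and DESeq2 called these 3 over all genes.

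The first principal component held 45.5% of the variance of the 500 most variable genes. Its largest loadings were those of Gm10800-group genes, led by Gm10800 (-0.144) and Gm10801 (-0.141). That group ranged from 4.22 to 16528 CPM between libraries. Scores on the first component ran from -49.7 to 0.24 in ko/ko and from -20.9 to 32.5 in wt/wt, and the difference did not pass the threshold (exact permutation p = 0.0794, all splits, two-sided). Within 10 Mb of Flg, 0 of 329 genes were called by edgeR and 6 by DESeq2 (6 higher, 0 lower), while weighted voom called 20 higher and 11 lower, and 16.1% had an unadjusted p under 0.05 against 15.3% elsewhere (Fisher's exact p = 0.643). Over all genes DESeq2 called 630 of 18404 and weighted voom 1802 of 18435, so neither called a larger share near Flg. The common biological coefficient of variation was 36.6% within wt/wt and 35.1% within ko/ko, a difference as large in 92 of 100 drawn splits (permutation p = 0.92).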

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

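The tests of the fibroblast pattern, the genotype test of the myeloid pattern, the split count of the weighted voom fit and that of edgeR calls in either direction were chosen only after the result was seen. In 82 groups of libraries tested for a single outlying value, 7 were found, and about 1 in 20 arises by chance (4.1 expected).

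Single libraries stood apart from their group for these values. The mitochondrial share was 6.30% in ko/ko replicate 1 against 1.81% to 2.01% in the other ko/ko libraries. The Gm10800 group of predicted genes reached 3151 CPM in wt/wt replicate 1 against 4.22 to 406 CPM in the other wt/wt libraries. In ko/ko replicates 1 to 4 this group had 5575, 34.2, 154 and 16528 CPM, and no single ko/ko library was flagged. The 20 most abundant genes took 19.0% of counts in wt/wt replicate 4 against 17.1% to 17.4%. Krt1 was 3.99 log2 CPM in ko/ko replicate 1 against 3.06 to 3.19. In wt/wt replicate 3, Foxc1 was 4.64 and 2700081O15Rik 3.80 log2 CPM, above the other wt/wt libraries. 3110080E11Rik was -2.79 log2 CPM in wt/wt replicate 5, which had its 1 wt/wt count. Spike-in sequences, used in no comparison, had 6 counts in wt/wt replicate 1, above the floor of 3 that a count of 0 allows, and 1 to 3 elsewhere.

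Small p-values were in excess, with 2816 genes under an unadjusted p of 0.05. Chance could not be excluded: 6 of 100 splits gave as many, and the highest other split gave 5434. Removing each library's trend on exon length left 15.3% of genes under 0.05, removing that on GC left 16.1%, and a Gm10800-group covariate left 13.8%, which argues against each as the whole cause. The splits with most genes set wt/wt replicates 1 and 2 and ko/ko replicate 1 apart from wt/wt replicates 3 to 5, which points to a structure of the libraries that does not follow genotype. The library identifiers run in separate blocks by genotype, so a processing batch and the genotype cannot be separated here.

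Chance was also weighed for the calls of edgeR and of the lists. At least 1 gene was called higher in 3 of 100 splits, the real one with 1 and the highest other with 753, but the direction of a split is arbitrary. Counted in either direction, 5 of 100 splits called at least 1 gene, the highest other 1329, so chance cannot be excluded for the call of Clmp. The 3 lists higher were matched in 72 of 100 splits (highest other 14) and the 4 lists lower in 53 of 100 (highest other 12), so chance cannot be excluded. The 1802 genes of the weighted voom fit were matched in 8 of 100 splits, the highest other with 3902.

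Myeloid and MHC class II genes were high in 3 of 4 ko/ko libraries. Immune cells carried through the sort may contribute: 11 other macrophage and dendritic cell genes, none in the myeloid list, had a median log2 fold change of 1.66 (exact 95% sign interval over genes 0.15 to 2.11, p = 0.0792 with an estimated correlation). All 11 were higher in ko/ko, 5 of them with an unadjusted p under 0.05 in edgeR's test. Fcgr3 had 3.73 against 0.527 CPM, while Ifi30, the most abundant, had 31.4 against 28.4 CPM and Coro1a 1.62 against 1.57 CPM. Of 7 granulocyte and mast cell markers 6 were positive (median 1.74, camera adjusted p = 0.0583, 0.846 with an estimated correlation), with scores of 2.13, 2.18, 1.08 and -1.43 in ko/ko replicates 1 to 4 and 1.40 in wt/wt replicate 1, and of 9 lymphocyte markers 7 were positive (median 0.30, adjusted p = 0.0982, 0.612 with an estimated correlation). Neither list passed. These values leave open both immune cells and class II induction without them, since the interval over the 11 genes runs from 0.15 to 2.11. The CD45-negative gate would remove such cells. Whether genotype sets the difference stays open, with an adjusted p of 0.612 with an estimated correlation.

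Fibroblast transcripts exceeded basal keratinocyte transcripts in 9 of 9 libraries, by 6.70 to 20.1 times, with Dcn at 10868 to 21870 CPM. Stromal cells among the sorted cells may account for this, although the labels name the cells epidermal, and the CD49f gate can keep other cells that carry this integrin. Genotype is argued against as the cause, since the excess was present in all 5 wt/wt libraries and the ratio did not differ past the threshold (exact permutation p = 0.77). A single mislabelled library is argued against by the same 9 of 9.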

How the results depend on the processing

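No paired analysis was possible because replicate numbers follow accession order only. The sex covariate was not run, since Xist and Y-linked counts put all 9 libraries in one class, and legacy=TRUE is this edgeR version's default and equals the reported fit. DESeq2 gives no list values. Of the alternatives below, legacy=FALSE, voom without weights, the 3 sets of left-out libraries, the Gm10800 covariate and the trend removals were chosen after seeing the data. The count of genes higher in ko/ko (1) moved to 4 with library size alone, 26 with no filter, 438 with DESeq2, 1217 with voom and quality weights, 98 with 1 surrogate variable, 2 with the Gm10800 covariate, 0 with the length trend removed and 28 at an adjusted p under 0.1. The count lower (0) moved to 2 with no filter, 192 with DESeq2, 585 with weighted voom, 20 with the surrogate variable, 1 with the Gm10800 covariate and 3 at an adjusted p under 0.1. Without the 3 libraries with most Gm10800-group reads, 7 genes were higher, Clmp not among them. Weighted voom gave wt/wt replicates 1 and 2 and ko/ko replicate 1 weights of 0.330, 0.425 and 0.351; voom without weights called 1 gene higher and 0 lower. Leaving out these 3 libraries, which have the lowest fibroblast shares, gave 1515 higher and 905 lower. Leaving out the wt/wt pair alone, a one-sided choice made on a measured value, gave 1108 and 527. Both sets were picked from the data, so their counts are not independent evidence. With library size alone, 78.0% of genes with an unadjusted p under 0.05 were higher, against 58.0% with TMM, 49.9% with the length trend removed and 51.9% with the GC trend removed, and the median of all genes moved from -0.03 to 0.08. With single libraries left out, genes higher ranged from 0 to 12 and genes lower stayed at 0. Lists higher (3) moved to 6 with no filter, 6 without the 3 Gm10800-rich libraries, 5 with the Gm10800 covariate and 6 with the length trend removed. They moved to 0 with an estimated correlation or fry's directional test, and single libraries left out gave 2 to 6. The interferon call ended without the wt/wt pair (adjusted p = 0.0899) and without the 3 low-fibroblast libraries (0.0984). Lists lower (4) moved to 11 with no filter, 2 with either voom fit, and 0 with an estimated correlation or fry's directional test. Single libraries left out gave 2 to 4 lists lower. Fry's mixed test, which allows both directions within a list, called 5 lists. The test direction of the cell cycle list turned with weighted voom (median 0.065), without wt/wt replicate 2 (-0.083; with single libraries left out the median reached -0.52), without the wt/wt pair (0.088) and without the 3 low-fibroblast libraries (0.22). The cause was not tested. The pooled Flg log2 ratio of -0.55 ranged from -1.70 to 0.11 with single libraries left out, within its counting interval. Named genes did not overlap, so their kept direction over 672 values was no test. Of these, 136 newly passed and 10, all of Clmp, no longer passed. Principal component, Flg neighbourhood and spread results kept their side of the threshold. Few counts, whose cause was not tested, limit what can be said of Flg and the cornified envelope genes.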

Other observations

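Fisher's exact test and the score of the clock genes were chosen only after the result was seen. The clock list was among the 37 fixed beforehand, and camera did not call it (adjusted p = 0.826, 0.943 with an estimated correlation). Fry's mixed test, which allows both directions, gave an adjusted p of 8.98e-05. Clock genes had positive and negative log2 fold changes, and 10 of 19 had an unadjusted p under 0.05, or 52.6% against 15.2% of other genes (Fisher's exact p = 0.000166, treating genes as independent). In edgeR's test adjusted over the list alone, 3 passed as higher and 4 as lower, and 0 passed over all genes. Over all genes DESeq2 called Cry2 (adjusted p = 0.00416) and Cry1 (0.0127) lower and Hlf (0.0276) higher, weighted voom called 3 higher and 2 lower, and the fit with 1 surrogate variable called Per2 lower (0.0416). Cry2 and Cry1, repressors of the clock, had log2 fold changes of -0.90 (SE 0.20) and -0.59 (SE 0.15), Per2 had -0.69 (SE 0.29), and Clock and Arntl, its activators, had 0.73 (SE 0.23) and 0.68 (SE 0.22). A score of 3 activator-side minus 7 repressor and output genes differed between the genotypes (exact permutation p = 0.0238, two-sided, all splits), but it was defined after these values were seen and restates them, so a difference in clock phase at sampling stays open. Sampling times are not given in the sources used here.

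Of the lymphatic endothelial genes Lyve1 and Mmrn1, neither passed edgeR's test over all genes, while DESeq2 called both lower (adjusted p = 2.82e-05 and 0.00111), as did weighted voom, and the fit with 1 surrogate variable called Lyve1 (0.0326). Mmrn1 averaged 44.9 ± 21.9 CPM (SD, n = 4) against 154 ± 79.8 CPM (SD, n = 5). Fewer lymphatic endothelial cells may explain this, but 10 other markers, whose values had not been seen when they were chosen and 8 of which were negative, had a median log2 fold change of -0.27 and a camera p of 0.108, which leaves it open. Prox1, Flt4, Ccl21a, Reln and Nts had -1.08, -0.96, -1.61, -0.79 and -0.47, and Nrp2, Stab1, Pdpn and Sema3d had -0.01, -0.03, -0.08 and 0.09. Itga9 had 0.56 (SE 0.14), in the opposite direction. DESeq2 called Ccl21a lower (adjusted p = 0.0173) and Itga9 higher (0.0116). The gate for CD49f does not exclude endothelium, which can carry this integrin.

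Cytoplasmic ribosomal protein genes, a list prompted by the values of 2 of its members, Rpl32 and Rps6, had negative log2 fold changes for 72 of 77 members (median -0.37), and 34 of the 77 had an unadjusted p under 0.05. No test of the list is given, since it holds the genes that prompted it. DESeq2 called 11 members lower, weighted voom 34 and the fit with 1 surrogate variable 0. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.16 with exon length. Malat1 ranged from 1520 to 10996 CPM between libraries, and tendon and cartilage matrix genes took 4.12% to 5.42% of counts.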
